A study of Gallus gallus with 32 samples.

How the data were processed

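Gene expression was measured on 32 arrays, each carrying RNA from the blood of 1 broiler chicken, with 16 birds on a control diet and 16 on a diet supplemented with comfrey. Each diet group held 8 females and 8 males. The labels describe RNA taken from ground, frozen blood clots with TRIzol and RNeasy columns, and biotin-labelled targets made with the GeneChip WT PLUS kit. The labels give an age of 32 under a unit of months for every bird, an unusual age for broilers, and no comparison used it. Dose, length of feeding and housing are not given in the sources used here.

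The deposited values are log2 probe set signals. Per the submitters' processing notes, they were made with GCOS 1.1.1 and RMA, which corrects background, normalizes quantiles across arrays and summarises probes into probe sets. The base of the logarithm was read from the values, which ran from 0.83 to 13.97 with array medians between 6.51 and 6.60 and interquartile ranges between 2.66 and 3.05. Correlations between any 2 arrays lay between 0.945 and 0.984. The genome build behind the probe annotation is not given in the sources used here. Arrays give no counts, so the number of arrays limits the precision. Raw intensities were not analysed here.

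The table of values held 20804 rows, of which 2910 were blank in every array and were left out. The reason for the blanks is not given in the sources used here, and 2110 of the blank rows list a gene. All 17894 remaining probe sets were tested without a filter. Control probe sets could not be told from others in the tables used here, so none was removed. Of the tested probe sets, 10264 carried exactly 1 gene symbol (9680 different genes), 182 carried several and 7448 carried none. Another 824 rows repeated the values of an earlier row in all arrays to 9 decimals, leaving 17070 different rows. All tested rows were kept in the counts, and counts of different rows are given beside the sex calls. Gene names and chromosomes came from a table of RefSeq genes of the assembly GRCg7b, matched by gene id for 9770 single-symbol probe sets, by symbol for 474 and by an older symbol for 15, while 5 stayed unmatched. Positions within chromosomes were not used.

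Groups, tests, gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. Each comparison was a linear model fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 to the deposited log2 values, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a call at an adjusted p under 0.05 without a fold threshold. The diet comparison (comfrey minus control) held sex as a covariate, and the sex comparison (male minus female) held diet. The interaction was the diet difference in males minus that in females. Diet differences within each sex came from a model with a mean per diet and sex, which shared its estimate of spread over all 32 arrays. Errors of fitted differences are standard errors (SE) and errors of group means are standard deviations (SD).

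There were 22 gene lists covering blood cell types, immune and stress responses, detoxification, mineral, iron and lipid metabolism, cell division, ribosomal proteins and W-linked genes. Comfrey, a medicinal plant, contains pyrrolizidine alkaloids, which liver enzymes can turn into DNA-damaging compounds. Each gene was represented by its probe set with the highest mean signal. Lists were tested with camera from limma, at its preset correlation between genes of 0.01 and again with the correlation estimated from the data, and with fry. P-values were adjusted over the 22 lists, or over 21 for sex, where the W-linked list was left out. Members of a list were also adjusted over the list alone. For each of diet, sex and interaction, the named genes were the 12 largest rises and the 12 largest falls among single-symbol probe sets past the threshold. For diet and sex, the sign had to be the same in both levels of the other factor. For sex, each 12 were taken as 6 on the sex chromosomes and 6 on autosomes. Where fewer than 12 passed in a direction, the places were filled by the smallest unadjusted p in that direction, and these genes are given as values that did not pass. Within each list, the 4 members with the smallest unadjusted p could be named.

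The heterophil minus lymphocyte score was, for each bird, the mean of standardized signals of the heterophil list minus that of the T cell and B cell lists. It was compared by two-sided permutation of diet within sex with 100000 resamples, or exactly over all 12870 splits within 1 sex. The male minus female difference was summarised as the median over single-symbol probe sets on Z, W and autosomes, with 95% intervals from 10000 bootstrap resamples over genes, which are not independent replicates. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

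The models were tested on simulated data of the same size and spread, with known differences of log2 0.25, 0.5 and 1 placed in 67, 67 and 66 of 17894 probe sets. For diet, 32.8%, 76.1% and 100% of them were recovered, with 3 false calls among 142. For the interaction the shares were 0%, 20.9% and 65.2%, with 0 false calls among 57. For diet within females they were 9%, 65.7% and 84.8%, with 2 false calls among 108. All came from 1 permutation of the birds' residuals, so the false calls give no error rate. Other splits of the real birds into diets, within sex, gave as many as 687 calls. The shares hold for differences of the 3 sizes placed together, since the adjustment depends on how many probe sets differ. In the simulated test of lists, camera with the preset correlation found a list shifted by log2 0.25, but also called 3 other lists with that shift and 1 of 22 without any shift.

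The alternatives were renewed quantile normalization, centring each array on its median, the probe sets brighter than the median probe set, single-symbol probe sets, means over the probe sets of a gene, a trended and robust variance model, array weights, bird number as a covariate or as a block of 1 to 16 against 17 to 32, the first residual component, blood cell scores, an estimated correlation, a single sex, an unadjusted p and leaving out each bird in turn. Counting identical rows once, lists without Z-linked and W-linked genes, leaving out both birds with the highest interferon levels, the list means per bird, the estimated correlation together with bird number, the score within a sex or its interaction without single birds, and the per-bird interactions with bird number in the model were chosen after seeing the data. Birds apart from the others in groups of 8 were found by the gap to the next bird over the range of the group (Dixon's ratio). Replicates were numbered in the order of the samples and pair nothing. Bird numbers come from the sample titles, and their meaning is not given there.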

Results

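Blood of 32 broiler chickens, labelled as whole blood cells and extracted from clots, was profiled, 1 array per bird, in 4 groups of 8: females and males on a control diet, and females and males on a diet with a comfrey supplement. Values are log2 signals, and 17894 probe sets had values in every array. The brightest named genes were HBAD and HBA1, the alpha globin chains of red cells, at 13.87 ± 0.08 and 13.67 ± 0.07 (SD, n = 32), followed by the iron store FTH1 at 13.51 ± 0.05. The array medians differed by under 0.1 between birds, and the number of arrays limits the precision.

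The first comparison asked which blood transcripts responded to dietary comfrey. No probe set passed the threshold between 16 comfrey-fed and 16 control birds (limma, lowest adjusted p 0.507), while 1429 had an unadjusted p under 0.05 against 894.7 that chance gives. Of these, 636 were higher and 793 lower on comfrey. Among 100 splits of the birds into diets, the real one included, 10 gave as many, so chance is not excluded. With the first residual component as a covariate, 38 probe sets passed, 9 higher and 29 lower on comfrey, with a component taken from the residuals of the same model. Most of the 38 did not carry exactly 1 gene symbol, and other splits of the birds were not run with that component. The 95% interval of the difference lay within a 2-fold change for 98.9% of probe sets and within log2 0.5 for 89.6%, with a median SE of 0.081. Differences below those sizes were not excluded.

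None of the genes with the smallest p passed the threshold in the model without that component, so the following are values only. With it, HSPA13, HSD17B11, ATG4C, EDARADD, RND2 and MIR1640 passed (adjusted p 0.0137 to 0.0487). HSPA13, a chaperone of the HSP70 family, averaged 9.50 ± 0.14 on comfrey and 9.21 ± 0.19 on control (SD, n = 16), a difference of 0.28 ± 0.058 (SE). HSD17B11, a steroid dehydrogenase, differed by 0.29 ± 0.066. ATG4C, a protease of autophagy, differed by 0.26 ± 0.062, TMEM43 by 0.26 and PFKFB2, which sets the level of a regulator of glycolysis, by 0.26. THRAP3, a splicing cofactor, had the largest positive difference among the 12 genes named in that direction, at 0.81 ± 0.22. EDARADD, EMC2, B4GALT4, NIPAL2 and ANGEL2 lay between 0.19 and 0.35. RND2 was at 0.32, with opposite signs in its 2 probe sets. On the negative side, ENPP2, the secreted enzyme autotaxin, averaged 2.97 ± 1.09 on comfrey and 4.32 ± 0.84 on control, a difference of -1.35 ± 0.33 near the low end of the signal range. The microRNA gene MIR1640 differed by -0.33 ± 0.080, the mRNA reader YTHDF2 by -0.21 ± 0.059 and AOX1, aldehyde oxidase, by -0.22 ± 0.062. POU4F1L, RPH3A, LLPH, UMODL1, S100B and FAM167B lay between -0.30 and -0.20, and CACNA1H was at -0.41 ± 0.11. For 24 genes named for diet, the adjusted p lay between 0.507 and 0.573.

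Among the gene lists, the interferon response list lay lower on comfrey and the ribosomal protein list slightly higher in camera with its preset correlation. Neither list held with an estimated correlation, where the adjusted p was 0.798 for both. In the interferon list, 24 of 25 measured genes had a negative difference, with a median of -0.22 and an adjusted p of 0.00115. Examples are CD274, the immune checkpoint ligand PD-L1, at -0.22 ± 0.095, and TAP1, which carries peptides to class I molecules, at -0.27 ± 0.12. In the ribosomal list 30 of 33 genes had a positive difference, with a median of 0.045 and an adjusted p of 0.00812. RPL38 was at 0.13 ± 0.066 and RPL23 at 0.12 ± 0.082. In both lists, 0 genes passed over all probe sets and 0 adjusted over the list alone. Without control replicate 16, a male, the adjusted p was 0.298 for either list. Leaving out single birds put the ribosomal list over the threshold in 6 of 32 cases.

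Detoxification genes were the one group with members past a threshold in their own list. That adjustment was made within each of the 22 lists and not across them, so a call in 1 list can arise by chance. In the xenobiotic metabolism list, 13 of 22 genes had a negative difference, and 2 passed adjusted over the list alone while 0 passed over all probe sets. These were NR1H4, the bile acid receptor FXR, at -0.17 ± 0.048 (list-alone adjusted p 0.0299) and the sulfotransferase SULT1C3 at -0.21 ± 0.070 (list-alone adjusted p 0.0491). Both had dim signals, at 4.28 and 3.36 on average. The aryl hydrocarbon receptor gene AHR1A was at 0.31 ± 0.11, and POR, the electron donor of cytochrome P450 enzymes, was at -0.54 ± 0.22. The list as a whole had a camera adjusted p of 0.473.

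The other lists gave no call for diet. In the antioxidant NRF2 list (adjusted p 0.218), 18 of 27 genes were positive, among them the glutathione peroxidase GPX4 at 0.32 ± 0.13 and PGD of the pentose phosphate pathway at 0.19 ± 0.068. In the DNA damage and p53 list (adjusted p 0.473), 14 of 19 were positive, with BTG2 at 0.17 ± 0.067. In the list of heat shock and unfolded protein genes (adjusted p 0.795), 14 of 27 were positive and CANX, the calnexin chaperone of the endoplasmic reticulum, was at 0.54 ± 0.16 with a list-alone adjusted p of 0.0658. Antigen presentation genes (adjusted p 0.473) were negative in 8 of 11, although BF2, the main class I heavy chain, was at 0.45 ± 0.16. The acute phase and complement list (adjusted p 0.218) was negative in 12 of 18, with C4 at -0.23 ± 0.074, and the inflammatory cytokine list (adjusted p 0.476) in 15 of 24, with the cytokine inhibitor SOCS3 at -0.24 ± 0.084. Calcium, phosphorus and vitamin D genes (adjusted p 0.218) were negative in 19 of 24, with the vitamin D hydroxylase CYP24A1 at -0.23 ± 0.098. Glucocorticoid response (adjusted p 0.562) and lipid genes (adjusted p 0.912) shared PDK4, a brake on pyruvate oxidation, at -0.50 ± 0.19. The iron list (adjusted p 0.434) included STEAP3, a ferrireductase, at 0.28 ± 0.11, and the cell cycle list had an adjusted p of 0.559. Among the blood cell lists, adjusted p was 0.218 for T cells, with CTLA4 at 0.27 ± 0.13, and 0.473 for thrombocytes and for cytotoxic cells. It was 0.635 for monocytes, 0.795 for the erythroid and B cell lists, 0.866 for the 2 W-linked genes and 0.973 for heterophils.

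**Figure D1:**
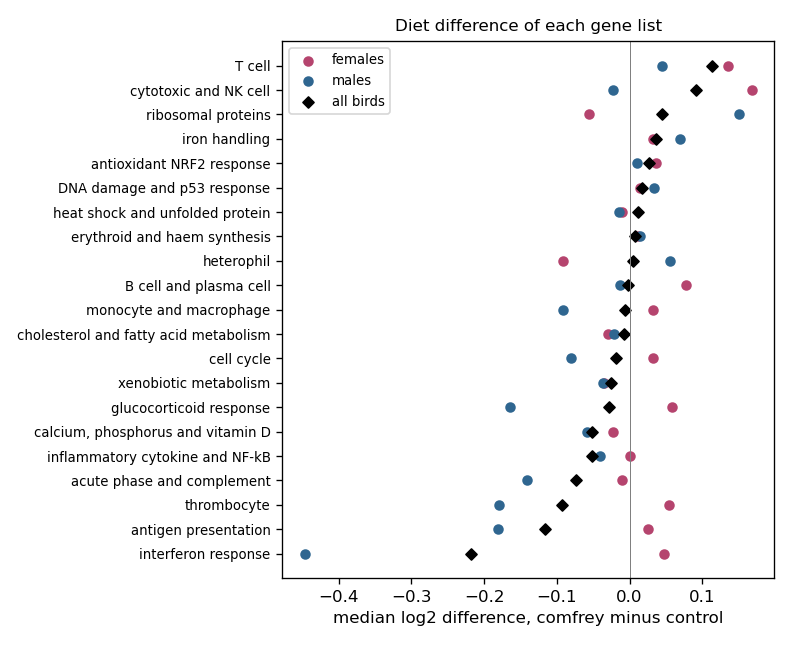
Median log2 difference between comfrey and control over the genes of each list (x axis), for 16 females, 16 males and all 32 birds. The interferon response list lies at -0.22 over all birds, at 0.048 in females and at -0.45 in males.

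The balance of heterophils and lymphocytes is a common blood measure of stress in poultry, and here it was read from marker transcripts. The heterophil minus lymphocyte score differed by -0.14 between diets (permutation p 0.556), which is smaller than the spread between birds. In females it averaged -0.42 ± 0.74 on comfrey and 0.16 ± 0.35 on control (SD, n = 8, exact permutation p 0.0502). Comfrey replicate 6, a female, had the lowest score, and without it the difference between females went from -0.589 to -0.365 (exact permutation p 0.138) and that between diets to -0.011 (permutation p 0.956). In males it averaged 0.29 ± 0.68 on comfrey and -0.029 ± 0.54 on control (SD, n = 8, exact permutation p 0.312). The difference between the sexes in this response was 0.91 (permutation p 0.037). Leaving out single birds gave 0.71 to 1.05, the lowest without comfrey replicate 6, and put its permutation p at 0.05 or more in 13 of 32 cases (highest 0.075). In a linear model its 95% interval reached 0 with bird number added (0.82, -0.10 to 1.75) or a block of birds 1 to 16 against 17 to 32 (0.89, -0.024 to 1.80). The heterophil side rests on 7 measured genes, among them SERPINB10B at an interaction of 0.72 ± 0.35.

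Within females, 1 gene passed the threshold between diets. CACNA1H, a subunit of T-type calcium channels, averaged 4.67 ± 0.25 on comfrey and 5.45 ± 0.36 on control (SD, n = 8), a difference of -0.78 ± 0.13 (limma, adjusted p 0.0242). In males the difference was -0.029, and the interaction of 0.75 ± 0.19 did not pass (adjusted p 0.488). The call was lost when only the 16 females were fitted, and leaving out single birds gave between 0 and 3 calls, the highest without control replicate 5. The count moved from 1 in 11 of 32 such cases, to 0 in all but that one. In females 704 probe sets had an unadjusted p under 0.05. In males no gene passed (lowest adjusted p 0.414), with 1850 at an unadjusted p under 0.05.

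The interaction asked whether the response to comfrey differed between the sexes. At the level of single genes it gave 0 calls (limma, lowest adjusted p 0.434), with 1020 probe sets at an unadjusted p under 0.05. Its genes are given as values that did not pass. PCCB and HIBCH, mitochondrial enzymes of amino acid breakdown, had interactions of 0.47 ± 0.11 and 0.37 ± 0.10. ATG7, which starts the lipid conjugation step of autophagy, was at 0.61 ± 0.15 and the selenium carrier SELENOP1 at 0.65 ± 0.16. The ubiquitin ligase scaffold CUL4A was at 1.90 ± 0.45 and WASHC4, of an endosomal complex, at 1.08 ± 0.27. RWDD3, LOC417551, LRRC59, DCAF4L2 and PPP2R3B lay between 0.43 and 1.03. On the negative side were SLC25A37, the mitochondrial iron importer mitoferrin, at -0.72 ± 0.22, the lymphocyte receptor S1PR4 at -0.39 ± 0.12 and the cytokine TNFSF15 at -0.39 ± 0.13. GUCA1B, KLHL38, MIR1774, LOC416169, SNX19, KCNS3, KCNH4, RANBP3L and SOX18 lay between -0.81 and -0.35, and the 2 probe sets of SOX18 had opposite signs. NFKB1, at 0.55 ± 0.16 (adjusted p 0.0395), passed in the inflammatory list and SLC25A37 (adjusted p 0.045) in the iron list, each adjusted over the list alone. SLC25A37 is also in the erythroid list, where 0 genes passed adjusted over the list alone. These adjustments were not made across the 22 lists, so such calls can arise by chance.

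In camera with the preset correlation, 3 lists passed for the interaction of diet and sex, and none passed with an estimated correlation. There the adjusted p was 0.633 for the interferon list, 0.239 for antigen presentation and 0.633 for ribosomal genes. The interferon list had a median of 0.048 in females and -0.45 in males, with a negative interaction in 25 of 25 genes (adjusted p 1.8e-06), such as LY6E at -0.77 ± 0.39 and CMPK2 at -0.73 ± 0.39. The antigen presentation list had a negative interaction in 10 of 11 genes, with a median of -0.20 (adjusted p 0.0141), and TAPBPL and TAP1, which act in the loading and transport of peptides, were at -0.34 ± 0.18 and -0.42 ± 0.24. The ribosomal list had a median of -0.056 in females and 0.15 in males, with a positive interaction in 32 of 33 genes (adjusted p 1.49e-10), such as RPS21 at 0.34 ± 0.12. In these lists 0 genes passed over all probe sets and 0 adjusted over the list alone. Bird number, an index in the sample titles, averaged 20.25 in control males and 15.25 in comfrey-fed males, and 12 in control females and 18.5 in comfrey-fed females. With bird number in the model, the adjusted p of camera with the preset correlation was 0.0854 for the interferon and antigen presentation lists and 8.26e-06 for ribosomal genes. With a block of birds 1 to 16 against 17 to 32, it was 0.00559, 0.0613 and 2.88e-08. The heterophil list had an adjusted p of 0.0197 and 0.00763 in these models. With an estimated correlation, its adjusted p was 0.464 and 0.491, and its mean per bird had an interaction p of 0.0947 (permutation, adjusted p 0.484). Without such a term, the heterophil list (adjusted p 0.0702), cell cycle list (adjusted p 0.105) and thrombocyte list (adjusted p 0.14) did not pass. The adjusted p of the other lists lay between 0.368 and 0.971.

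The level of interferon genes varied more between males than between females. Their mean per bird was 8.94 ± 0.18 in control females, 8.97 ± 0.12 in comfrey-fed females, 9.53 ± 0.81 in control males and 9.07 ± 0.47 in comfrey-fed males (SD, n = 8). Control replicate 16 stood at 11.38, and the next control male at 9.56. Between males the diets differed by -0.46 (exact permutation p 0.185, n = 8), and by -0.20 without that bird (exact permutation p 0.371). Without that bird the camera adjusted p of the interaction was 0.0271 for the interferon list and 0.0681 for antigen presentation.

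The mean of antigen presentation genes was 9.00 ± 0.12 in control and 8.84 ± 0.09 in comfrey-fed males, and 8.72 ± 0.07 in control and 8.80 ± 0.05 in comfrey-fed females (SD, n = 8). Against control, comfrey-fed males thus lay lower by a difference of -0.16 (exact permutation p 0.00373) and comfrey-fed females higher by 0.079 (exact permutation p 0.0227). Relative to the brighter named genes, the differences were -0.19 in males (exact permutation p 0.00497) and 0.064 in females (exact permutation p 0.153), where the females no longer passed. The 2 differences were themselves apart by -0.24 (permutation p 0.00012, adjusted over 22 lists 0.00264), a test of the list means chosen after the camera result was seen. In the same test the adjusted p was 0.484 for the interferon and ribosomal lists.

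**Figure D2:**
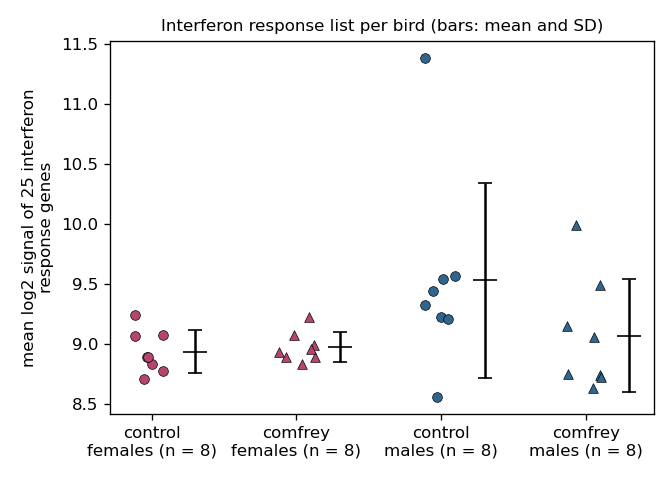
Mean log2 signal of 25 interferon response genes in each bird (y axis) by diet and sex, with bars for the mean and SD of 8 birds. Control males run from 8.56 to 11.38, and comfrey-fed males from 8.63 to 9.99.

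Sex had a far larger imprint on blood than diet. Between 16 males and 16 females 958 probe sets passed (limma), 631 higher and 327 lower in males, covering 842 different rows and 496 named genes. Male birds carry a pair of Z chromosomes and females a single copy. Among single-symbol probe sets with a known chromosome, more rises lay on Z than on all autosomes together, while 425 of the 958 called probe sets carried no gene name. Of 447 Z-linked probe sets, 206 were higher and 4 lower in males, against 178 and 110 of 9772 on autosomes. The median male minus female difference was 0.28 on Z (95% interval 0.21 to 0.36) and -0.014 on autosomes. Among the 204 Z-linked probe sets brighter than the median probe set it was 0.55 (0.53 to 0.60), a 1.47-fold excess, and among the 243 dimmer ones it was 0.017. The Z-linked median was 0.24 in control birds and 0.32 in comfrey-fed birds.

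Genes on W, the chromosome only females carry, gave the largest differences. HINTW averaged 12.28 ± 0.23 in females and 5.21 ± 0.20 in males (SD, n = 16), and 0 birds lay on the side of the other sex. LOC430766, LOC427025, UBAP2L2 and ATP5F1AW, also on W, were lower in males by log2 differences of -6.14, -5.89, -3.30 and -1.59, and LOC427353, placed on Z, by -2.58. Of 16 W-linked probe sets, 9 passed, all lower in males. The named Z-linked genes higher in males were ALDH7A1, an aldehyde dehydrogenase, at 1.54 ± 0.31, PTCD2 at 1.24 ± 0.079, HACD4 at 1.19 ± 0.26, INIP at 1.16 ± 0.075, GDA, guanine deaminase, at 1.15 ± 0.24 and SNCAIP at 1.06 ± 0.20.

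**Figure D3:**
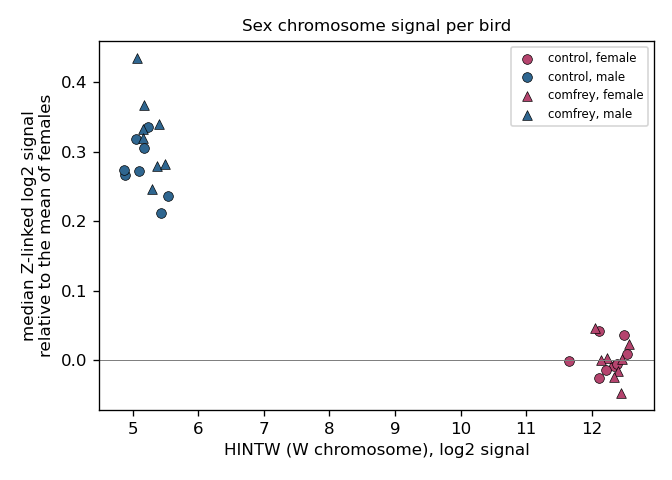
Median Z-linked signal relative to the mean of females (y axis, log2) against HINTW signal (x axis, log2), 1 point per bird with 8 birds in each diet and sex. Males lie between 0.21 and 0.43 on the y axis and females between -0.048 and 0.046.

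Autosomal genes also differed between the sexes. Higher in males were GSTK1, a glutathione transferase, at 0.96 ± 0.27, the serotonin receptor HTR2A at 0.89 ± 0.26, XCL1, a chemokine of cytotoxic lymphocytes, at 0.87 ± 0.18, and the neurofilament NEFL at 0.86 ± 0.15. SELE, an adhesion receptor, and CYR61, a matrix protein, were both at 0.84, with SE of 0.25 and 0.21. Lower in males were the phosphate transporter SLC20A1 at -1.07 ± 0.28, XK, a red cell membrane protein, at -0.94 ± 0.21, GTSF1, of the piRNA pathway, at -0.85 ± 0.16, WAPL, which releases cohesin, at -0.55 ± 0.088, and the kinase YES1 at -0.54 ± 0.14. DYNC2H1, a dynein of cilia, was at -0.58 ± 0.18 with an adjusted p of 0.05 after rounding.

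In 5 of 21 lists camera with the preset correlation gave a call, all higher in males. With an estimated correlation, the adjusted p was 0.644 for all 5 lists. The thrombocyte list (adjusted p 0.00928, median 0.22) had 12 of 17 genes positive and 2 past the threshold, the fibrinogen receptor subunit ITGB3 at 0.74 ± 0.22 and GP1BB, of the von Willebrand factor receptor, at 0.49 ± 0.14. The interferon list (adjusted p 0.000546, median 0.31) had 23 of 25 positive and 0 past the threshold. Its adjusted p was 0.0141 without control replicate 16. Without that male and comfrey replicate 3, which had the highest interferon means, the interferon and cell cycle calls were lost (adjusted p 0.0643 for each), a setting chosen after seeing the data. Heat shock and unfolded protein genes (adjusted p 0.00928) had 20 of 27 positive and 3 past the threshold, the Z-linked chaperone DNAJA1 at 0.67 ± 0.074, its partner in the HSP70 system BAG3 at 0.79 ± 0.11 and the endoplasmic chaperone HSPA5 at 0.34 ± 0.085. The cell cycle list (adjusted p 0.0498) had 22 of 28 positive and 1 past the threshold, the replication helicase gene MCM4 at 0.36 ± 0.11. Ribosomal proteins (adjusted p 1.23e-08, median 0.14) had 31 of 33 positive and 5 past the threshold, including the Z-linked RPS23, RPL37 and RPL17 at 0.78, 0.54 and 0.86 and the autosomal RPL23A at 0.32. Adjusted over the list alone, 5 thrombocyte, 0 interferon, 6 heat shock and 11 ribosomal genes were higher, and 1 cell cycle gene was higher and 1 lower. Without genes on Z or W, the adjusted p was 0.0124 for thrombocytes, 0.000482 for interferon, 0.0402 for heat shock, 0.0323 for cell cycle and 0.000184 for ribosomal proteins. With an estimated correlation, it was 0.646 for these 5 lists. Leaving out single birds put the cell cycle list over the threshold in 17 of 32 cases. With a block of birds 1 to 16 against 17 to 32, the calls for thrombocytes (adjusted p 0.101) and cell cycle (0.186) were lost. With bird number in the model, the cell cycle call was lost (0.106) and the thrombocyte call was not (0.0045). The interferon, heat shock and ribosomal lists passed in both models.

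The lists without a call held single genes that differed by sex. In the erythroid list (adjusted p 0.434), the Z-linked FECH, which inserts iron into haem, rose by 0.45 ± 0.051 and ALAS1, the first enzyme of haem synthesis outside red cells, by 0.19 ± 0.059, while XK and the transcription factor TAL1 (-0.39 ± 0.11) fell. The iron exporter SLC40A1 rose by 0.54 ± 0.087 (iron list, adjusted p 0.483). In the lipid list (adjusted p 0.901), the Z-linked ABCA1 and STARD4, both carriers of cholesterol, rose by 0.87 ± 0.053 and 0.40 ± 0.080. The Z-linked peptidase ERAP1 rose by 0.85 ± 0.075 (antigen presentation, adjusted p 0.0581) and the Z-linked interleukin 7 receptor IL7R by 0.57 ± 0.12 (T cells, adjusted p 0.0712). In the DNA damage list (adjusted p 0.596), the Z-linked PLK2 rose by 0.80 ± 0.16 and GADD45A by 0.34 ± 0.079. The chemokine receptor CXCR1 rose by 0.28 ± 0.079 (heterophils, adjusted p 0.138) and SOD1 by 0.17 ± 0.052 (antioxidant list, adjusted p 0.667). The lists of cytotoxic cells, with XCL1 (adjusted p 0.243), and of calcium and phosphorus genes, with SLC20A1 (adjusted p 0.113), had 1 gene past the threshold each. No gene passed in the monocyte (adjusted p 0.739), B cell (0.667), inflammatory (0.483), xenobiotic (0.739), glucocorticoid (0.692) or acute phase lists (0.139).

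Thrombocyte genes also followed bird number across the 32 birds. The mean standardized signal of 17 thrombocyte genes rose with bird number, with Pearson's r at 0.735 (permutation p 3e-05) and Spearman's rho at 0.733 (permutation p 3e-05), and an adjusted p of 0.00066 over 22 lists. The permutations moved bird number over all 32 birds, without regard to diet or sex. Without the 2 birds farthest from the median number r was 0.705. It was 0.715 in females, 0.788 in males, 0.801 on control and 0.689 on comfrey. Within birds 1 to 16 it was -0.066 and within birds 17 to 32 it was 0.494, so the relation did not hold within the first 16. The meaning of the number is not given in the sources used here.

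**Figure D4:**
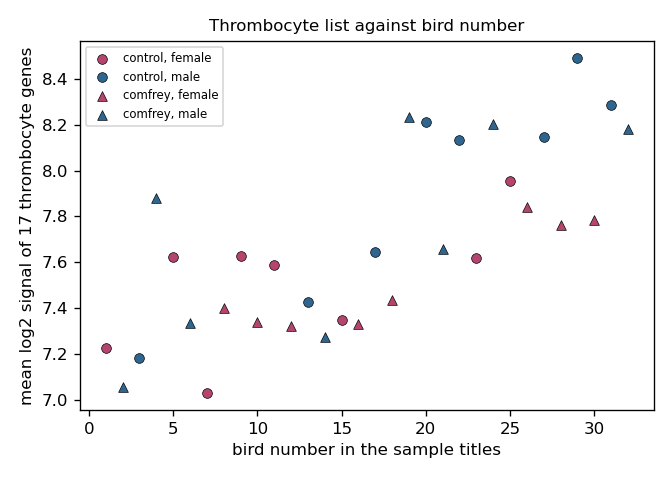
Mean log2 signal of 17 thrombocyte genes (y axis) against the bird number in the sample titles (x axis), 1 point per bird, coloured by sex and shaped by diet. The correlation of the standardized mean with bird number is 0.735 over all 32 birds and -0.066 within birds 1 to 16.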

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

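Tests of the interferon levels without single birds, of array correlations, of the antigen presentation means and of birds apart from the rest were chosen after the results were seen. The rules for other splits were set before the counts were seen, except those for diet calls, diet calls in males and interaction calls, which were written when these were known to be 0. The test of array quality was set before its value was seen.

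The interaction of diet and sex in the interferon list had an adjusted p of 1.8e-06 in camera with the preset correlation, and did not pass with an estimated correlation (adjusted p 0.633) or with bird number in the model (adjusted p 0.0854). With the block of 16 in the model, camera gave an adjusted p of 0.00559 at the preset correlation and 0.957 with an estimated one. The list mean differed by -0.46 in males (exact permutation p 0.185) and by 0.039 in females (exact permutation p 0.623), and in control males the gap between control replicate 16 and the next bird was 0.644 of the range of the group, which is larger than chance gives in 19 of 20 groups of 8. Leaving that bird out brought the difference between males to -0.198 (exact permutation p 0.371), so a single bird with a high interferon level may account for more than 0.5 of the difference. Without it and comfrey replicate 3, the highest comfrey-fed male, the difference was -0.33 (exact permutation p 0.0862), so a response shared by the other males stays open. Poor quality of that array stays open too: its median deviation from its group ranked 9 of 32, past the bound of 8 set beforehand by only 1 rank, although the 8 arrays that deviated more had interferon means between 8.56 and 9.49, and its median correlation with other arrays was the lowest of 32 (0.9609, next 0.9637), also without the interferon list (0.9619).

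In that bird, 23 of 25 interferon genes were at their highest over all birds, against 566 of 9680 named genes. MX1, an antiviral GTPase, reached 11.99 against a mean of 7.94 in the other 7 control males, and OASL, an antiviral protein that senses RNA, 12.13 against 8.26. CH25H and SOCS1, both induced by interferon, stood 3.80 and 3.39 above the other control males. Whether the bird was ill at sampling was not tested.

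The interaction of the antigen presentation list had an adjusted p of 0.0141 in camera with the preset correlation. It did not pass with an estimated correlation (adjusted p 0.239), with bird number (0.0854) or the block of 16 (0.0613) in the model, or without control replicate 16 (0.0681). The difference of the list means per bird was -0.24 (permutation p 0.00012, adjusted over 22 lists 0.00264), and -0.20 without control replicate 16 (permutation p 0.00036). It was -0.22 without TAP1, which is shared with the interferon list (permutation p 0.00082) and -0.25 relative to the brighter named genes (permutation p 0.00169), where the difference in females alone no longer passed (0.064, exact permutation p 0.153). With bird number in a linear model of the means it was -0.23 (95% interval -0.37 to -0.096). All 8 comfrey-fed females lay above the median control female, and 4 of 8 comfrey-fed males below the lowest control male. The interaction of the ribosomal list had an adjusted p of 1.49e-10 in camera with the preset correlation and 0.633 with an estimated correlation, and its mean per bird had one of 0.20 (permutation p 0.0659, adjusted over 22 lists 0.484). The heterophil minus lymphocyte score differed in its response by 0.91 (permutation p 0.037), and by 0.82 (95% interval -0.10 to 1.75) with bird number in a linear model.

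Among 96 groups of 8 birds (the list means, the score and CACNA1H by diet and sex), 6 held a bird apart from the rest by the same measure, where chance gives 4.8. Besides the interferon list, these were antigen presentation in control males, at 0.581 of the range, with the highest bird at 9.28 and the next at 9.04. The W-linked list in comfrey-fed males was at 0.792, with the lowest bird at 4.95. B cell genes in comfrey-fed males were at 0.552, with the highest bird at 7.43 and the next at 7.19. Iron handling in comfrey-fed males was at 0.544, with the lowest bird at 9.24. Cell cycle genes in comfrey-fed females were at 0.531, with the highest bird at 6.72 and the next at 6.65. Control replicate 16 was the bird apart for both interferon and antigen presentation genes, and comfrey replicate 12 for both B cell and iron genes. The groups are thus not independent, which leaves the chance count at 4.8 but its spread unknown.

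Other splits of the same birds into diets, within sex, tell how far chance reaches. For the 0 calls for diet, for diet in males and for the interaction, the comparison decides nothing, since any split gives at least 0 (100 of 100 for each). The highest other counts were 687, 468 and 220. For diet, 10 of 100 splits gave as many probe sets at an unadjusted p under 0.05 as the 1429 found (highest other 4747), so chance is not excluded. The 1 call in females was matched by 8 of 100 splits (highest other 2), which does not exclude chance. The 2 lists called for diet were matched by 70 of 100 splits (highest other 8), and the 3 lists called for the interaction by 54 of 100 (highest other 8), so chance is not excluded for these. Splits with as many as 687 calls point to a structure of the birds other than diet. For sex, 1 of 100 splits within diet, the real one, gave 958 calls (highest other 2). Likewise, 1 of 100 gave a Z-linked median as large as 0.28 (highest other 0.18). Chance is thus unlikely for both, at the lowest share that 100 splits can give. The 5 lists called for sex were matched by 24 of 100 splits (highest other 10), which does not exclude chance.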

How the results depend on the processing

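Counts of calls for diet in males, sex calls other than those listed here, the marker score and the Z-linked median other than in brighter probe sets stayed within 1.5 times their values, or on their side of the threshold, under each setting run. Diet calls stayed at 0 except with the first residual component as a covariate, where they were 38, 9 higher and 29 lower, among them HSPA13, CANX and HSD17B11. That component comes from the residuals of the same model, so it lowers the spread and leaves the differences as they were (HSPA13 0.28 with an SE of 0.058 before and 0.050 after). At an unadjusted p under 0.05, diet gave 1429 and the interaction 1020. The 1 call in females fell to 0 with renewed quantile normalization, with blood cell scores and with the 16 females alone, where fewer birds estimate the spread. Among brighter probe sets the count was 0, which decides nothing, since CACNA1H is dimmer than the median probe set and was not tested there. Sex calls were 507 with single-symbol probe sets and 496 with means per gene, since fewer probe sets were tested, and between 656 and 1304 otherwise, sharing 598 of 656 with blood cell scores, 907 of 1014 with bird number and 896 of 987 with array weights. The Z-linked median rose to 0.554 in brighter probe sets. Lists called for diet were 1 with renewed quantile normalization and with brighter probe sets, and 0 with array weights and with an estimated correlation. Lists called for sex were 3 with brighter probe sets and with birds in blocks of 16, 2 with blood cell scores, which left the thrombocyte, heterophil, T cell and B cell lists out of the family, and 0 with an estimated correlation. Lists called for the interaction were 6 with the first residual component and 0 with an estimated correlation. Leaving out both birds with the highest interferon levels, a setting chosen after seeing the data like the counts of identical rows and lists without sex-linked genes, gave 3 lists for sex, without the interferon and cell cycle lists. Leaving out 1 bird at a time gave 820 to 990 sex calls and 0 to 1 interaction calls, the highest without comfrey replicate 16. It gave 0 to 3 calls in females, the highest without control replicate 5, and 0 to 3 lists for diet, the lowest without control replicate 16 and the highest without comfrey replicate 2. It gave 4 to 7 lists for sex and 2 to 6 for the interaction, the lowest without control replicate 16 and the highest without control replicate 2, and scores between -0.21 and -0.011 (permutation p 0.346 to 0.956). Among named genes, 247 of 253 alternative values for diet kept their direction and side of the threshold and 6 passed it. For sex 242 of 254 did and 12 values in 5 genes (DYNC2H1, HTR2A, SELE, GSTK1 and YES1) no longer passed. For the interaction 249 of 250 did, and SOX18 reversed to 0.007 with means over its 2 probe sets, which have opposite signs. Where no reason is given here, the cause was not tested. The variance model, array weights, residual component and cell scores were not run for the marker score, which is not fitted across genes. In Z-linked probe sets dimmer than the median probe set the median was 0.017, and background was not measured.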

Other observations

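The tests of a lower share of red cells, through a shared rise of white cell genes, and of Z-linked genes by brightness were chosen after the values were seen.

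Bird number went with a gain of genes of thrombocytes, the nucleated clotting cells of birds. Per 10 birds, 9 of 17 thrombocyte genes rose in limma, led by GP9, a subunit of the von Willebrand factor receptor, by 0.90 ± 0.11 (SE), with the transcription factor FLI1 by 0.40 ± 0.051, RGS18, a brake on receptor signalling, by 0.66 ± 0.090, and F13A1, which crosslinks fibrin, by 0.67 ± 0.11. Across all genes 857 probe sets passed for bird number beside diet and sex in limma, 511 upward and 346 downward. This count was not set against permuted bird numbers, and other splits of the birds into diets gave as many as 687 calls. The list passed camera with the preset correlation (adjusted p 2.23e-14) and with an estimated one (adjusted p 0.0206 with an estimated correlation). T cell genes (r = 0.646, adjusted p 0.00088) and cytotoxic genes (r = 0.561, adjusted p 0.00455, permutation tests over 22 lists) rose too, with estimated-correlation adjusted p of 0.077 and 0.155. Spearman's rho was 0.650 and 0.628, and r without the 2 farthest birds 0.616 and 0.508. Within birds 1 to 16 and 17 to 32, r was 0.477 and 0.198 for T cells and 0.547 and 0.009 for cytotoxic genes. The relation was not limited to blood cell lists: DNA damage (r = 0.541, adjusted p 0.0101), interferon (r = 0.424, adjusted p 0.0298), cell cycle (r = 0.432, adjusted p 0.0363) and glucocorticoid genes (r = 0.442, adjusted p 0.0363) also passed upward, and acute phase genes downward (r = -0.46, adjusted p 0.032). For these, Spearman's rho was 0.520, 0.548, 0.497, 0.431 and -0.455, and r without the 2 farthest birds was 0.519, 0.436, 0.397, 0.440 and -0.387. The 2 birds were picked by number, so control replicate 16, bird number 31 with the highest interferon level, stayed in. Within birds 1 to 16 and 17 to 32, r was 0.25 and -0.156 for DNA damage, 0.084 and 0.376 for interferon, 0.232 and 0.204 for cell cycle, 0.044 and -0.302 for glucocorticoid and -0.504 and 0.216 for acute phase genes, so the sign changed between the sets for DNA damage, glucocorticoid and acute phase genes. For interferon, r was 0.654 on control and 0.093 on comfrey. With an estimated correlation in camera, their adjusted p lay between 0.0909 and 0.47.

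Bird number is spread unevenly over diet and sex. The slopes were fitted beside both, but the correlations and their permutation tests took all birds together, without regard to diet or sex. Within females and males, r was 0.715 and 0.788 for thrombocytes, and 0.728 and 0.321 for DNA damage genes. No other biological factor that follows bird number is given, so none was tested. With the first residual component as a covariate, 87.2% of the median slope of thrombocyte genes was left. That component was not shown to measure brightness, so a general brightness of the arrays stays open. The second component followed bird number more closely (r = 0.755) than the first (r = -0.462) and was not used as a covariate. A lower share of red cells as the only cause is argued against by 3 of 5 other white cell lists. Their slope intervals lay below 0.5 of the thrombocyte slope of 0.30 per 10 birds (95% interval 0.21 to 0.40). Heterophils were at 0.037, monocytes at 0.040 and B cells at 0.026. The lists were not matched for brightness: the median signal was 8.55 for thrombocyte genes and 7.28, 6.66 and 7.29 for these 3. Cytotoxic genes were dimmer still, at 6.15. T cell genes at 0.128 and cytotoxic genes at 0.225 rose more, and the erythroid list was at -0.037 (95% interval -0.093 to 0.018). A part played by the share of red cells therefore stays open. A step between birds 1 to 16 and 17 to 32, as 2 days or 2 batches of sampling might leave, stays open (permutation p of the slope within these sets 0.177).

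The excess of Z-linked signal in males grew with brightness. In 4 sets of 111 or 112 Z-linked probe sets, from the dimmest to the brightest, the median male minus female difference was -0.011, 0.058, 0.43 and 0.596. Loss of signal in the background could lower the excess of dim probe sets, but it is argued against as the cause of an excess below 2-fold, since the brightest set had a 95% interval of 0.55 to 0.64, below the log2 of 1 that a full dosage difference gives. Compression of bright signals by the array and a partial compensation of Z dosage between the sexes would both give such a value, a 1.51-fold excess. Neither was tested, and both stay open.

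Some genes varied between birds, beside the fitted differences of diet and sex, far beyond the median residual SD of 0.206 of named genes. MAGOH had an SD of 1.97 and ranged from 2.00 to 7.91, LOC417058 ranged from 6.79 to 13.07, CFTR from 2.05 to 8.06, SLC13A3 from 5.21 to 9.70 and CDH2 from 5.94 to 11.26.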
